A study of Homo sapiens with 86 samples.

How the data were processed

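RNA from 86 liver biopsies was extracted with a Qiagen column kit, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The deposited table holds intensity values of 49386 probe sets, which the authors summarised with RMA, per the submitters' processing notes, with the version not given in the sources used here. RMA corrects background, normalizes arrays to a common distribution and summarises probes, so differences in total RNA between biopsies are not kept. The values ran from 1.14 to 16699.4 and were on a linear scale. The plan written before the data were examined had assumed log2 values, so log2 was taken first, with no pseudocount.

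Probe sets were named from the platform annotation, with symbols updated by gene identifier. Of the 49386 probe sets, 45259 had 1 symbol, 1327 had several and were not used, and 2800, of which 93 are controls, had none. Of 18239 symbols 61 had no match in the reference table, and 42 sex-linked genes were left out. For each of the remaining 18197 genes the probe set with the highest mean was kept, and the lowest 25% of genes, with a mean log2 intensity under 2.62, were left out, which left 13648. On an array the number of samples and the signal over background limit precision. Of the tested genes, 7.79% had a mean above that of the brightest of 23 nonspecific control probe sets (7.16 on the log2 scale), whose signal depends on their base content. All 13648 lay above the median of the means of these controls (1.88).

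Groups were taken from the disease labels: 6 steatosis, 13 mild acute hepatitis and 67 cirrhosis samples. Nothing in the labels says whether samples of a group came from different patients, so the p-values measure only the spread between these samples, which may be technical. Correlation between arrays ran from 0.519 to 0.973 with a median of 0.934, and no arrays were identical. Group means were fitted in 1 model over all 86 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust). Adjusted p values are Benjamini-Hochberg values and the threshold was 0.05. Fold changes are differences of mean log2 intensity, with standard errors from the fit.

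Lists of genes for 33 pathways and cell types, fixed before the data were examined from general knowledge of the liver, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The genes named in the text follow a rule fixed beforehand. It takes a panel of 10 liver genes, the 5 largest rises and 5 largest falls among genes past the threshold, the 2 members with the smallest adjusted p of the 6 lists with the smallest camera p, and at most 2 members of other lists. Sex-linked, immunoglobulin, T cell receptor and unnamed genes were passed over. Some genes of these lists had no probe set with a symbol of their own or lay under the filter, and were not analysed here.

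The fit was tested on simulated data for the 13648 genes, in which 67, 67 and 66 genes per comparison were changed by 1.5-, 2- and 4-fold. Noise was drawn independently for each gene and array from a normal distribution with the gene's own spread. The simulation thus held no correlated genes, no noisy arrays and no differences between stretches, so its rates need not hold for the real arrays. Changes of 1.5-, 2- and 4-fold were recovered in 11.9%, 65.7% and 100% of genes for hepatitis against steatosis, in 28.4%, 77.6% and 100% for cirrhosis against steatosis, and in 67.2%, 98.5% and 100% for cirrhosis against hepatitis, and unchanged genes made up 3.28%, 5.52% and 4.32% of the calls. Array quality was compared with two-sided permutation tests, exact where steatosis was involved and with 100000 resamples otherwise (Python 3.11.15, numpy 2.4.6 and numba 0.67.0), and figures were drawn with matplotlib 3.10.9.

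The labels give no batch. The order of the records was used only to define 3 stretches of 6, 31 and 49 arrays as a possible batch, and the fits with the stretch were chosen after the data were examined. So were the fit without hepatitis samples 11 and 12, and the 100 random splits made within stretches, which add to the 100 random splits of all samples compared. Other alternatives covered the choice of probe set, the filter, the eBayes settings, array weights, the groups in the fit, quality covariates, left-out arrays, normalization, a fold minimum, the replicate number as a block, left-out samples and 20 draws of 13 cirrhosis samples.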

Results

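Gene expression was measured in 86 human liver biopsies that had been fixed in formalin and embedded in paraffin, each on its own Affymetrix array. The labels placed 6 biopsies in a steatosis group, 13 in a group with mild acute hepatitis and 67 in a cirrhosis group, all from alcoholic liver disease. Steatosis is the build-up of fat in liver cells, acute hepatitis is inflammation with liver cell injury, and cirrhosis is the scarred, nodular end stage. The comparisons ask how the liver transcriptome differs between these stages. After 1 probe set was chosen per gene and the dimmest 25% were left out, 13648 genes were tested, and 721 of them differed among the 3 groups in limma's moderated F test.

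No difference in the mean spread of relative log expression was found between the groups when stretches of records were pooled, but their median log2 intensity after RMA differed slightly. The interquartile range of the relative log expression, a measure of array noise, was 0.613 ± 0.103 (SD, n = 6) in steatosis, 0.709 ± 0.261 (SD, n = 13) in hepatitis and 0.627 ± 0.263 (SD, n = 67) in cirrhosis. None of its 3 differences passed a permutation test, with adjusted p of 0.526, 0.883 and 0.444 for hepatitis against steatosis, cirrhosis against steatosis and cirrhosis against hepatitis. A limit of 0.820 for outlying arrays was exceeded by 0 of 6 steatosis, 3 of 13 hepatitis and 5 of 67 cirrhosis arrays. The median log2 intensity of an array was 3.68 ± 0.02 (SD, n = 6) in steatosis, 3.71 ± 0.04 (SD, n = 13) in hepatitis and 3.75 ± 0.03 (SD, n = 67) in cirrhosis. Cirrhosis arrays lay 0.06 above steatosis arrays (two-sided exact permutation test, adjusted p = 4.47e-05 over 6 tests) and 0.04 above hepatitis arrays (two-sided permutation test, adjusted p = 0.00141).

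The labels name no array batch, but the records were divided into 3 stretches, and the groups are spread unevenly over them. The cuts were placed by disease label in record order, after the 2 early hepatitis arrays and at the first steatosis array. The second stretch therefore holds only cirrhosis, and all steatosis arrays lie in the last, by construction. The first stretch holds 4 cirrhosis and 2 hepatitis arrays, the second holds 31 cirrhosis arrays, and the last holds 32 cirrhosis, 11 hepatitis and all 6 steatosis arrays. The cre spike-in exceeded the bioB spike-in by 5.46 ± 0.13 (SD, n = 6) on the log2 scale in the first stretch, against 4.12 ± 0.42 (SD, n = 31) and 4.15 ± 0.35 (SD, n = 49) in the others. It thus did not set the second stretch apart from the last. The 3′ probe set of GAPDH exceeded its 5′ probe set, a sign of RNA breakdown, by 1.24 ± 0.19 (SD, n = 31) in cirrhosis of the second stretch and by 0.95 ± 0.17 (SD, n = 32) in cirrhosis of the last. The bile duct and ductular list score of cirrhosis samples averaged 0.60 ± 0.72 (SD, n = 31) in the second stretch and -0.18 ± 0.62 (SD, n = 32) in the last, and the drug metabolism score averaged -0.49 ± 0.71 (SD, n = 31) and 0.23 ± 0.36 (SD, n = 32). The counts of genes in each comparison are therefore also given with the stretch as a block and within the last stretch. Since the cuts follow the labels, a fall in calls with the block cannot be put down to a batch alone.

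**Figure D1:**
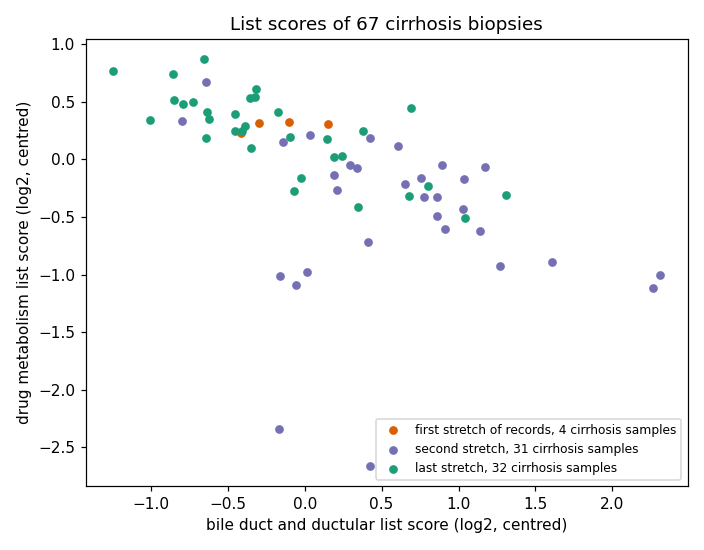
Mean centred log2 level of the bile duct and ductular list (horizontal axis) and of the drug metabolism list (vertical axis) in 67 cirrhosis biopsies; each point is a biopsy coloured by its stretch of records. The mean bile duct score was 0.60 in the second stretch and -0.18 in the last, and the mean drug metabolism score was -0.49 and 0.23.

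In mild acute hepatitis compared with steatosis, matrix genes lay higher and hepatocyte genes lower, but no single gene passed the test. Of 32 extracellular matrix genes tested, 31 had a positive log2 fold change, with a median of 0.62. LUM, which encodes the collagen-binding proteoglycan lumican, differed by 1.34 ± 0.52 (SE), and COL14A1, a fibril-associated collagen, by 0.91 ± 0.36 (SE), both with an adjusted p of 0.994. All 22 secreted hepatocyte plasma proteins had a negative value, with a median of -0.29. The coagulation factor genes F11 and F10 differed by -0.75 ± 0.30 (SE) and -0.53 ± 0.29 (SE). The sizes of both depended on few hepatitis samples. The matrix score was 1.23 and 1.42 in replicates 11 and 12 and lay between -1.20 and -0.21 in the other 11. With both left out, a choice made after seeing the data, the mean of the matrix list was 0.35 in place of 0.64 (preset camera adjusted p = 3.39e-05), LUM was at 0.96, COL1A1 at 0.52, SPP1 at 0.38 and CXCL8 at 1.02. With all samples the matrix list had an adjusted p = 0.448 with an estimated correlation. Without replicate 9, the hepatitis array of highest noise (1.41), the mean of the plasma protein list was -0.17 in place of -0.31 (preset adjusted p = 0.0226), and with all samples that list had an adjusted p = 0.473 with an estimated correlation.

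Metabolic lists lay on the same side as the plasma proteins. The urea cycle and amino acid list had a median of -0.35 over 19 genes, with NAGS, which makes the activator of the cycle, at -0.69 ± 0.26 (SE) and OTC, a urea cycle enzyme, at -0.83 ± 0.38 (SE). The mitochondrial respiratory chain list had a median of -0.21, and 1 of its 29 genes was positive. Its members with the smallest p were UQCRC1 at -0.53 ± 0.22 (SE) and NDUFV1 at -0.34 ± 0.21 (SE). Without replicate 9 the mean of the urea cycle list was -0.22 in place of -0.37 (preset adjusted p = 0.0142), that of the respiratory chain -0.10 in place of -0.21 (preset adjusted p = 0.0478), OTC was at -0.47 and NDUFV1 at -0.20. With all samples these lists had an adjusted p = 0.473 and 0.511 with an estimated correlation. The metallothionein list, of small metal-binding proteins, had a median of -0.78 over 7 genes and a mean of -0.82. Its preset call, which had an adjusted p = 0.473 with an estimated correlation, was lost without hepatitis replicate 2 (mean -0.52, adjusted p = 0.0633) and without steatosis replicate 6 (mean -0.55, adjusted p = 0.0785). Immediate-early genes had a median of 0.20, with MYC at 0.87 ± 0.34 (SE) and IER3 at 1.02 ± 0.40 (SE), and 1 steatosis sample lay apart from the others in IER3. The TNF and NF-kB list had a median of 0.15 and 19 of 20 positive values, including TNFAIP8 at 0.78 ± 0.35 (SE) and TNFRSF12A at 0.88 ± 0.42 (SE). With hepatitis replicates 11 and 12 both left out its mean was 0.18 in place of 0.31. With an estimated correlation the immediate-early list had an adjusted p = 0.448 and the TNF list an adjusted p = 0.452.

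Of the genes fixed beforehand as a liver panel, the neutrophil chemokine CXCL8 differed by 1.57 ± 0.77 (SE) and the collagen gene COL1A1 by 1.03 ± 0.50 (SE). CYP7A1, the rate-limiting enzyme of bile acid synthesis, differed by -1.47 ± 0.73 (SE). ALB, CYP2E1, CRP, KRT7, SPP1, PLIN2 and CD163 differed by -0.22, -0.40, -0.13, 0.21, 0.65, 0.06 and -0.12, and the adjusted p of the 10 panel genes was 0.994 or 0.995.

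By limma, 0 of 13648 genes passed, 593 had an unadjusted p under 0.05 where 682.4 would be expected by chance, and the smallest adjusted p was 0.208. Adjusted over the list alone, 1 stellate cell gene (THY1, 1.20 ± 0.35, SE) and 1 oncofetal gene (AKR1B10, 2.32 ± 0.79, SE) passed. Camera with a preset correlation placed 23 of 33 lists apart from the other genes, 12 higher and 11 lower, with the matrix list first (adjusted p = 2.40e-15). With an estimated correlation none of the 23 held, the matrix list included (adjusted p = 0.448 with an estimated correlation), and random splits of these samples gave a median of 8 preset calls. The balance depended in part on the noisiest arrays, since 12 lists, 10 higher and 2 lower, were called without the 8 arrays of highest noise, and 14, 10 higher and 4 lower, with array weights. It moved the other way without hepatitis replicates 11 and 12, whose noise (0.64 and 0.69) lay under the limit: 18 lists were called, 7 higher and 11 lower. Leaving out 1 sample ended 10 of the 23 calls in at least 1 case. With the stretch as a block and within the last stretch 0 genes passed. Without steatosis replicate 4, 1 gene passed, NCAM2 at -1.90 ± 0.37 (SE, adjusted p = 0.0247), which was singled out after its value was seen. With 6 steatosis samples, simulated changes of 2-fold were recovered in 65.7% of genes and changes of 1.5-fold in 11.9%. The simulation had independent genes and no noisy arrays, so recovery in the real arrays may differ.

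In cirrhosis compared with steatosis, 10 of 32 matrix, 4 of 22 stellate and 4 of 19 bile duct genes rose, and 3 of 13 sinusoidal endothelial, 3 of 20 bile acid, 2 of 21 fatty acid oxidation and 2 of 28 lipogenesis genes fell. No list held with an estimated correlation, and the falling members named from these lists (CLEC4M, CLEC4G, AMACR, AKR1D1, ACADS, ACAA1, DGAT2 and PLIN1) lost the call with the stretch as a block, though CLEC4G, AMACR, ACADS and DGAT2 passed within the last stretch. The 5 largest rises were in EFEMP1, GEM, SOD3, LUM and IGFBP1. EFEMP1, a matrix glycoprotein of the fibulin family, was 6.17-fold higher (log2 fold change 2.63 ± 0.60, SE, adjusted p = 0.0102), and LUM was 5.37-fold higher (2.42 ± 0.45, SE, adjusted p = 0.00134). The 5 largest falls were in BBOX1, NCAM2, PLIN1, AKR1D1 and CACNA1H. BBOX1, the last enzyme of carnitine synthesis, changed by -2.05 ± 0.53 (SE, adjusted p = 0.0253), and NCAM2, a neural cell adhesion molecule, by -1.94 ± 0.31 (SE, adjusted p = 1.58e-04).

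Of the 32 matrix genes, 10 rose, 0 fell and 28 rose when adjusted over the list alone. The median of the list was 0.99, and FBLN5, an elastic fibre protein, rose by 1.70 ± 0.34 (SE). The list had an adjusted p = 0.106 with an estimated correlation. Of 22 stellate cell and myofibroblast genes, 4 rose, and 11 rose and 2 fell when adjusted over the list alone. PDGFRA, a growth factor receptor of mesenchymal cells, rose by 1.74 ± 0.35 (SE) and THY1 by 1.44 ± 0.30 (SE). This list had an adjusted p = 0.142 with an estimated correlation.

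Of 19 bile duct and ductular genes, 4 rose, 0 fell and 11 rose when adjusted over the list alone, with a median of 1.03. SOX9, a transcription factor of ductular cells, rose by 2.08 ± 0.41 (SE), and the water channel AQP1, which the vascular endothelial list also holds, by 2.25 ± 0.44 (SE). The list had an adjusted p = 0.117 with an estimated correlation. The duct keratin gene KRT7 differed by 1.14 ± 0.43 (SE, adjusted p = 0.149) and SPP1, a secreted matrix protein, by 1.03 ± 0.52 (SE, adjusted p = 0.342). Under the block the mean of the list was 0.70 in place of 1.05, KRT7 was at 0.64 and SPP1 at 0.37.

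The endothelial lists had medians of opposite sign. Of 13 liver sinusoidal endothelial genes, 3 fell, 0 rose and 10 fell when adjusted over the list alone, with a median of -1.05. The lectin genes CLEC4M and CLEC4G fell, with log2 fold changes of -1.65 ± 0.38 (SE) and -1.32 ± 0.31 (SE). Of 15 vascular endothelial genes, 3 rose, and 6 rose and 1 fell when adjusted over the list alone. PLVAP, a diaphragm protein of fenestrated endothelium, rose by 1.86 ± 0.35 (SE). The sinusoidal list had an adjusted p = 0.106 and the vascular list an adjusted p = 0.142 with an estimated correlation. Under the block the mean of the sinusoidal list was -0.64 in place of -0.98.

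Hepatocyte metabolism lay lower in most of its lists, by less when the stretch was a block. Of 21 fatty acid oxidation genes, 2 fell and 9 fell when adjusted over the list alone. ACADS and ACAA1, enzymes of fatty acid breakdown, had log2 fold changes of -0.83 ± 0.20 (SE) and -0.89 ± 0.25 (SE), and in each 1 steatosis sample lay apart from the others. Of 28 lipogenesis and lipid droplet genes, 2 fell and 5 fell when adjusted over the list alone. These were DGAT2, which makes triglyceride, at -1.65 ± 0.36 (SE), and PLIN1, a lipid droplet coat protein, at -1.84 ± 0.51 (SE). Of 20 bile acid genes, 3 fell and 8 fell when adjusted over the list alone, among them AMACR at -1.12 ± 0.25 (SE) and AKR1D1 at -1.81 ± 0.45 (SE). The adjusted p values with an estimated correlation were 0.207 for fatty acid oxidation, 0.210 for lipogenesis and 0.210 for bile acids. Under the block the means of these 3 lists were -0.28, -0.22 and -0.27 in place of -0.52, -0.39 and -0.55, and PLIN1 was at -1.11.

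No gene of alcohol and acetaldehyde metabolism passed over all genes, while 12 of 15 fell and 1 rose when adjusted over the list alone. CAT and ALDH2 differed by -1.12 ± 0.33 (SE, adjusted p = 0.0547) and -0.93 ± 0.29 (SE, adjusted p = 0.0682), and the list had an adjusted p = 0.207 with an estimated correlation. Of 19 drug metabolism genes 0 passed and 4 fell when adjusted over the list alone. CYP1A2 and UGT2B7 differed by -2.07 ± 0.66 (SE, adjusted p = 0.0765) and -0.91 ± 0.30 (SE, adjusted p = 0.0873), and this list too had an adjusted p = 0.207 with an estimated correlation. Under the block the mean of the alcohol list was -0.32 in place of -0.76 and that of the drug metabolism list -0.33 in place of -0.68, with CAT at -0.66 and UGT2B7 at -0.53. Single members passed in the immediate-early list (MYC, 1.12 ± 0.29, SE), the TNF and NF-kB list (TNFRSF12A, 1.28 ± 0.36, SE), the oncofetal list (GOLM1, 1.01 ± 0.30, SE) and the glucose production list (IGFBP1, which binds insulin-like growth factors, 2.42 ± 0.66, SE). The glucose production list had a median of -0.22 and did not pass camera (adjusted p = 0.671), and the other 3 had an adjusted p = 0.152, 0.272 and 0.117 with an estimated correlation. Under the block TNFRSF12A was at 0.85, GOLM1 at 0.66 and the mean of the immediate-early list at 0.25 in place of 0.43.

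No gene of the fixed panel passed. CYP7A1 differed by -2.08 ± 0.63 (SE, adjusted p = 0.0601), CYP2E1 by -1.22 ± 0.51 (SE, adjusted p = 0.205), COL1A1 by 1.22 ± 0.43 (SE, adjusted p = 0.125) and CXCL8 by 1.73 ± 0.67 (SE, adjusted p = 0.166). ALB, CRP, PLIN2 and CD163 differed by -0.27, 0.26, -0.21 and -0.24, and with the stretch as a block these were -0.11, -0.30, -0.40 and -0.0207. The block put CYP7A1 at -1.15, CYP2E1 at -0.59 and CXCL8 at 1.10. Lists of macrophages, T and NK cells, cell cycle, ribosomal proteins and interferon-stimulated genes had medians of -0.01, 0.11, -0.01, -0.00 and 0.13, and none passed camera. The mean of the cell cycle list was 0.05, of the other sign than its median.

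By limma, 257 genes passed, 170 higher and 87 lower in cirrhosis. RNA breakdown went with the groups when stretches were pooled, in a difference that was not tested: the GAPDH 3′ excess was 1.09 ± 0.23 (SD, n = 67) in cirrhosis, 0.86 ± 0.29 (SD, n = 6) in steatosis and 0.91 ± 0.38 (SD, n = 13) in hepatitis, and that of ACTB 1.90 ± 0.45, 1.56 ± 0.35 and 1.55 ± 0.31. Within the last stretch the means were 0.95, 0.86 and 0.81 for GAPDH and 1.85, 1.56 and 1.51 for ACTB. GAPDH also went with the stretch, at 1.24 in cirrhosis of the second. In the first it was 1.03 in cirrhosis (n = 4) and 1.45 in hepatitis (n = 2). With the GAPDH difference as a covariate, which thus also carries part of the stretch, 98 genes passed, 79 higher and 19 lower. Camera placed 20 of 33 lists apart with the preset correlation, 8 higher and 12 lower, and 0 with an estimated correlation. Random splits of these samples gave a median of 8 preset calls. With the stretch as a block 38 genes passed, and within the last stretch 55 did. All 38 were among the 257, and all 257 kept their direction under the block. LUM, SOD3, GEM, NCAM2, PLVAP, FBLN5, AQP1, SOX9, PDGFRA and THY1 passed with the block. EFEMP1, IGFBP1, BBOX1, PLIN1, AKR1D1, CACNA1H, CLEC4M, CLEC4G, ACADS, ACAA1, AMACR, DGAT2, MYC, TNFRSF12A and GOLM1 did not. Among these 15 the block left a median of 74.1% of the log2 fold change (range 55.2% to 88.8%) and of 91.5% of the SE. Of the 15, 5 (ACADS, AMACR, CACNA1H, DGAT2 and EFEMP1) still had an unadjusted p under the largest one called without the block (9.39e-04), and lost the call because the adjustment was stricter with fewer genes passing. The other 10 had a larger p. EFEMP1 was at 2.29 ± 0.58 (SE, adjusted p = 0.0522), ACADS at -0.74 ± 0.19 (SE, adjusted p = 0.0513), CACNA1H at -1.41 ± 0.38 (SE, adjusted p = 0.0765), BBOX1 at -1.13 ± 0.38 (SE, adjusted p = 0.198) and AKR1D1 at -1.02 ± 0.31 (SE, adjusted p = 0.136) with the block. Within the last stretch 4 of the 15 passed by limma, CLEC4G with an adjusted p = 0.0226, AMACR at -0.86 ± 0.19 (SE, adjusted p = 0.0215), ACADS at -0.75 ± 0.18 (SE, adjusted p = 0.0407) and DGAT2 at -1.15 ± 0.27 (SE, adjusted p = 0.0303). The count also fell to 63 without steatosis replicate 5, and to between 106 and 152 without each of the other 5 steatosis samples. Of the 25 named genes called, 12 lost the call in at least 1 such case, with 82.7% to 110% of the log2 fold change and adjusted p up to 0.170. ACAA1, PLIN1, TNFRSF12A and GOLM1 lost it without any of the 6, and GOLM1 also without most single hepatitis samples. IGFBP1 lost it without replicates 1 to 5, BBOX1 without 1, 3, 5 or 6, MYC without 1, 2 or 3, AKR1D1 without 2, 5 or 6, ACADS and CLEC4M without 5 or 6, CLEC4G without 2 and EFEMP1 without 5. Centring each array on its median gave 114 higher of 237 in place of 170 of 257.

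**Figure D2:**
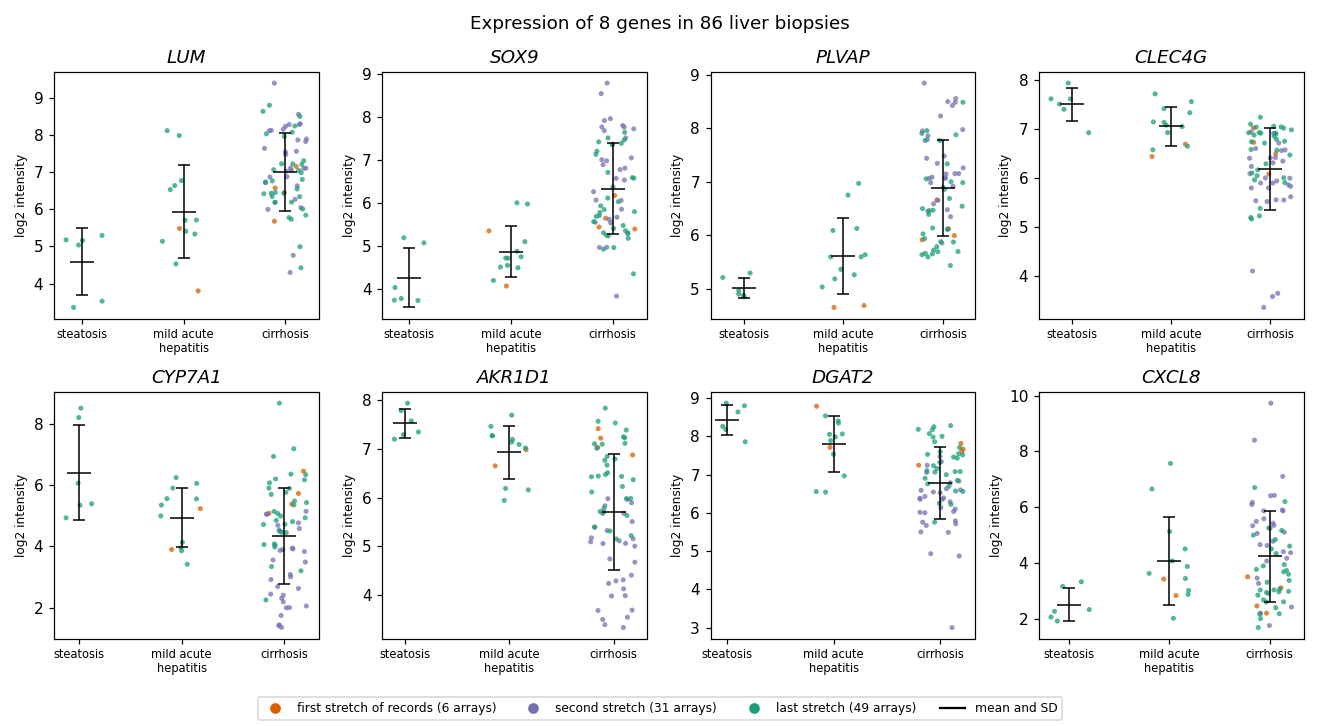
Log2 intensity of 8 genes (vertical axes) in the 6 steatosis, 13 mild acute hepatitis and 67 cirrhosis biopsies (horizontal axes); each point is a biopsy coloured by its stretch of records, and black bars give the mean and SD. Mean LUM was 4.59 in steatosis and 7.02 in cirrhosis, mean CLEC4G was 7.49 and 6.18, and the AKR1D1 points of cirrhosis lie lower on average in the second stretch than in the last.

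In cirrhosis compared with mild acute hepatitis, 5 of 19 bile duct genes rose and 6 of 13 sinusoidal endothelial genes fell, but neither list held with an estimated correlation. With the stretch as a block 3 of the 323 genes called passed, none of them a member of either list, while SOX9 of the bile duct list passed within the last stretch (1.18 ± 0.28, SE, adjusted p = 0.0354). The 5 largest rises were in CFTR, SLC38A1, ACSL4, C7 and SOX9. CFTR, the chloride channel of bile duct cells, was 3.51-fold higher (1.81 ± 0.39, SE, adjusted p = 0.00756), and SOX9 was 2.77-fold higher (1.47 ± 0.29, SE, adjusted p = 0.00446). The 5 largest falls were in CYP1A2, PLIN1, BBOX1, ALDH1L1 and AKR1D1. CYP1A2, a cytochrome P450 of drug metabolism, changed by -1.74 ± 0.47 (SE, adjusted p = 0.0272), and ALDH1L1, a folate enzyme, by -1.25 ± 0.27 (SE, adjusted p = 0.00701).

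Of 19 bile duct genes, 5 rose, 0 fell and 13 rose when adjusted over the list alone, with a median of 0.86 and an adjusted p = 0.309 with an estimated correlation. Of 13 sinusoidal endothelial genes, 6 fell, 0 rose and 9 fell when adjusted over the list alone, with a median of -0.78 and an adjusted p = 0.188 with an estimated correlation. FCN3, a ficolin of the lectin complement pathway, was at -1.22 ± 0.26 (SE, adjusted p = 0.00701) and CLEC1B at -1.21 ± 0.27 (SE, adjusted p = 0.00804). Of 32 matrix genes 2 rose, COL4A2 by 0.80 ± 0.22 (SE) and LUM by 1.08 ± 0.32 (SE), and 10 rose when adjusted over the list alone. The matrix list had an adjusted p = 0.673 with an estimated correlation. With hepatitis replicates 11 and 12 both left out, its mean was 0.70 in place of 0.41 (preset adjusted p = 4.66e-14), LUM was at 1.47 and COL1A1 at 0.70 in place of 0.19. Under the block the mean of the bile duct list was 0.42 in place of 0.78, and it passed with the preset correlation, while that of the matrix list was 0.20 in place of 0.41 and did not (preset adjusted p = 0.104). FCN3, CLEC1B and COL4A2 were then at -0.63, -0.65 and 0.47.

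Smaller numbers passed in the lists of lipid and alcohol metabolism. Of 28 lipogenesis genes 3 fell and 4 fell when adjusted over the list alone, including DGAT2 at -1.02 ± 0.26 (SE) and ACACB, an acetyl-CoA carboxylase, at -0.62 ± 0.16 (SE). Of 21 fatty acid oxidation genes 1 fell and 2 fell when adjusted over the list alone. ACADS was at -0.67 ± 0.14 (SE), and PDK4, which restrains glucose oxidation, was at -0.74 ± 0.25 (SE, adjusted p = 0.0770). Of 15 alcohol metabolism genes 0 passed and 2 fell when adjusted over the list alone, with ADH1C at -0.94 ± 0.30 (SE, adjusted p = 0.0663) and ADH4 at -1.10 ± 0.39 (SE, adjusted p = 0.101). These 3 lists had the same adjusted p = 0.673 with an estimated correlation. Under the block they also lost the preset call, with means of -0.10 in place of -0.26 for lipogenesis, -0.0422 in place of -0.25 for fatty acid oxidation and 0.0227 in place of -0.43 for alcohol metabolism. DGAT2 was then at -0.46, ACACB at -0.32, PDK4 at -0.32, ADH1C at -0.36 and ADH4 at -0.11.

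Elsewhere, the scavenger receptor MSR1 of macrophages fell (-0.76 ± 0.18, SE), as did the mitotic gene CDC20 (-0.49 ± 0.14, SE, and -0.41 with adjusted p = 0.0934 when replicates 11 and 12 were both left out) and the bile acid genes AKR1D1 (-1.22 ± 0.32, SE) and AMACR (-0.61 ± 0.17, SE). PDGFRA rose by 1.15 ± 0.25 (SE), HAND2 by 0.44 ± 0.13 (SE), PLVAP by 1.27 ± 0.25 (SE), AQP1 by 1.22 ± 0.31 (SE), the protease inhibitor A2M by 1.03 ± 0.23 (SE) and the hepatocyte transcription factor ONECUT1 by 0.61 ± 0.13 (SE). No panel gene passed. KRT7 came nearest, at 0.93 ± 0.30 (SE, adjusted p = 0.0711). ALB, CYP2E1, CYP7A1, CRP, COL1A1, SPP1, CXCL8, PLIN2 and CD163 differed by -0.05, -0.82, -0.61, 0.40, 0.19, 0.38, 0.16, -0.27 and -0.12. With hepatitis replicates 11 and 12 both left out, CRP, COL1A1, SPP1, CXCL8, PLIN2 and CD163 were at 0.82, 0.70, 0.65, 0.71, -0.15 and 0.09. With the stretch as a block ALB, CYP7A1, CRP, COL1A1, SPP1 and CXCL8 had the other sign, at 0.10, 0.34, -0.35, -0.04, -0.35 and -0.61, CD163 was at 6.07e-04, KRT7 at 0.47, CYP2E1 at -0.15 and PLIN2 at -0.55.

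By limma, 323 genes passed, 245 higher and 78 lower in cirrhosis, and 190 of them changed by at least 1.5-fold. Camera placed 12 of 33 lists apart with the preset correlation, 2 higher and 10 lower, and 0 with an estimated correlation. Random splits of these samples gave a median of 9 preset calls. With the stretch as a block 3 genes passed, of which MSR1 was at -0.89 ± 0.18 (SE, adjusted p = 0.0285). The others, EPB41L4A at 0.91 and ZNF844 at 0.72, were named after their values were seen. Within the last stretch 61 genes passed, among them MSR1, SOX9, C7 (1.11 ± 0.27, SE, adjusted p = 0.0465) and ONECUT1 (0.58 ± 0.14, SE, adjusted p = 0.0354) and none of the other 22 named genes called, and within the first stretch, which holds 2 hepatitis arrays, 52 did. The sinusoidal list had a mean of -0.37 with the block against -0.70 without it. It passed with the preset correlation in both, but without the block it had an adjusted p = 0.188 with an estimated correlation, and within the first stretch its mean was 0.09. PLIN1, BBOX1, AKR1D1, AMACR and CLEC1B were also above 0 there, at 0.75, 0.64, 0.32, 0.27 and 0.01. Without mild acute hepatitis replicates 1, 7 and 8 in turn, 205, 212 and 210 genes passed, and with 11 and 12 both left out 584 did. With the block, the 25 named genes that lost the call kept a median of 67.3% of the log2 fold change (range 24.7% to 107%) and 95.4% of the SE. BBOX1 was at -0.31, AKR1D1 at -0.36, PLIN1 at -0.59, CYP1A2 at -0.87, ALDH1L1 at -0.71, AMACR at -0.32 and SLC38A1 at 0.94 with it, and 8 of the 25 still had an unadjusted p under the largest one called without it (0.00117). Of 26 named genes called, 10 lost the call without 1 sample, with 83.5% to 103% of the log2 fold change and adjusted p up to 0.132. BBOX1 lost it without any steatosis sample or any hepatitis replicate but 9, 11 and 12, LUM without 1 to 8, CDC20 without 1, 4, 6 to 9 or 11 to 13, AMACR without 1, 3, 4, 5, 7 or 8, COL4A2 without 1, 2, 5, 7, 8 or 10, PLIN1 without 4 to 8 or 13, HAND2 without 5, 7, 8, 10 or 13, CYP1A2 without 1, 2, 8 or 10, AQP1 without 1 and ACACB without 8. Centring each array on its median gave 171 higher of 287 in place of 245 of 323.

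**Figure D3:**
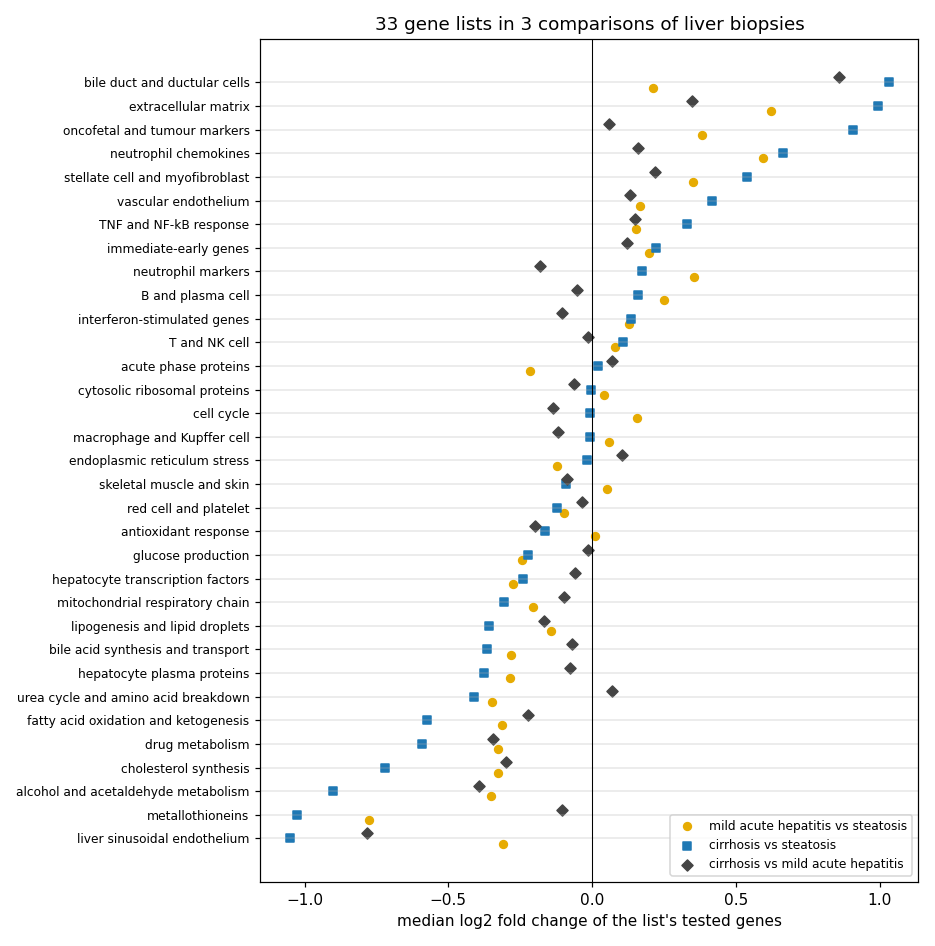
Median log2 fold change (horizontal axis) of each of 33 gene lists (vertical axis) in the 3 comparisons, with a marker per comparison and lists ordered by cirrhosis against steatosis. The bile duct list lay at 1.03 and the sinusoidal endothelial list at -1.05 in cirrhosis against steatosis, and at 0.86 and -0.78 in cirrhosis against mild acute hepatitis.

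The fold changes of hepatitis and of cirrhosis, each against the same 6 steatosis samples, correlated across the 13648 genes with r = 0.71 and a covariance of 0.0664. Genes are not independent replicates. In 100 simulated draws of unchanged groups with a shared reference group, the median r was 0.80 (range 0.35 to 0.96). The median covariance of these draws was 0.0378 (range 0.0144 to 0.243). Each draw shuffled the arrays of all groups, so its reference group was not the 6 steatosis samples. The draws therefore cannot show how much of the observed r comes from sharing those samples. With the steatosis samples split 3 and 3 between the comparisons, the median r over 20 splits was 0.24 (range 0.08 to 0.40) and the median covariance 0.0307. Since 0 genes passed in hepatitis, the overlap of calls was 0, as was that of independent lists.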

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

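The tests of handling, hepatocyte share and the bile duct part of RNA integrity between the stretches, and all 3 tests of the endothelial scores, were chosen after the results were seen, as were the division into stretches and the splits within stretches. Among the 6 steatosis samples, 50 values (named genes and array measures) were checked for a sample far from the rest, and 3 stood out, where chance flags about 1 in 20 groups. In IER3 the lowest sample, replicate 4, lay at 2.11 while the others lay between 2.95 and 3.37, a gap of 0.667 of the range. In ACADS replicate 1 was lowest at 6.58 against 6.79 to 6.84, a gap of 0.816 of the range. In ACAA1 replicate 2 was highest at 10.36 against 9.28 to 9.55, a gap of 0.746 of the range. The hepatitis and cirrhosis groups, of more than 10 samples, were not tested for this.

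Chance splits of the same samples were compared with each count. The first splits ignored the stretches, and the second were made within them and fitted with the stretch as a block. For hepatitis against steatosis any split reaches the real 0 genes (100 of 100, highest other 4, and 5 within stretches), so the count says nothing about chance. Its 23 lists were reached by 1 of 100 splits, the real one (highest other 20, median 8), and its 22 lists with the block by 2 of 100 (highest other 22, median 9). Both lie under the bound of 5 in 100 set for these tests, so chance is unlikely for a count of preset calls. The medians show that shuffled groups also gave many preset calls, and 0 of the 23 held with an estimated correlation. For cirrhosis against steatosis the 257 genes were reached by 1 of 100 splits (highest other 3) and the 20 lists by 4 of 100 (highest other 23, median 8). These tests were not corrected for their number. Where the stretch is ignored, chance is thus unlikely for the genes. For the lists 4 of 100 also lies under the bound, but so near it that chance is not excluded in uncorrected tests. With the block, the 38 genes were reached by 1 of 100 splits (highest other 20), but the 18 lists by 19 of 100 (highest other 27, median 10). With the stretch held fixed chance is thus unlikely for the genes and not excluded for the lists. For cirrhosis against hepatitis the 323 genes were reached by 3 of 100 splits, but the highest other split called 3625 genes, which points to a structure among the samples other than the groups. With the block the real count was 3, reached by 1 of 100 splits (highest other 0). Chance is thus unlikely for the gene count with the block. For the 323 genes 3 of 100 also lies under the bound, but these splits ignored the stretch and reached far higher counts, so chance is not excluded. The 12 lists of this comparison were reached by 38 of 100 splits (highest other 23, median 9), and its 5 lists with the block by 75 of 100 (highest other 24, median 9), so chance is not excluded for them. The 721 genes of the F test were reached by 4 of 100 splits (highest other 5303), which points to the same, and the 61 genes that passed in that test with the stretch as a block were reached by 1 of 100 (highest other 2).

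The cirrhosis samples of the second and last stretches differed in 2771 of 13648 genes by limma, 911 higher and 1860 lower in the second stretch. Handling that acts on genes by their signal level alone was examined with random lists of matched signal, and 20 of 33 lists lay outside their central 95%. Genes of a list vary together (estimated correlation 0.56 for the matrix list), unlike randomly drawn genes. List means therefore spread more than those of random lists whatever the cause, and this count cannot decide. A smaller hepatocyte share as the only change would raise all other cell types, but the sinusoidal endothelial list was lower by 0.71 (log2 difference -0.71, 95% interval -0.98 to -0.43) while the bile duct list was higher by 0.77 (0.44 to 1.11). A smaller share joined to a sinusoidal fall would give the same values, and the test cannot tell these apart. RNA integrity may account for part of it, since with the GAPDH and ACTB probe differences and array noise as covariates, the drug metabolism difference kept 39.8% of its size and the calls fell to 268, while the bile duct difference kept 82.3% (0.64, 0.20 to 1.07). What remains open is a handling batch that acts by signal level, by sequence or by RNA integrity in ways these measures miss. A smaller hepatocyte share joined to other changes stays open too, as does a difference between the patients. The labels give no group of patients, so no other biological explanation was tested.

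The vascular endothelial score was higher and the sinusoidal score lower in cirrhosis than in steatosis. A smaller endothelial share as the only change would lower both. The vascular score, without genes that other lists hold, was higher by 0.36 (95% interval 0.12 to 0.60), against -0.98 (-1.51 to -0.46) for the sinusoidal score. This value restates the pattern, which was seen before the test was chosen, so it is no separate test of that explanation. The stretch is not the whole cause, since the difference between the scores was 0.96 (0.37 to 1.55) within the last stretch, against 1.34 (0.67 to 2.02) in all samples. With 3 quality covariates the difference was 0.99 (0.36 to 1.61), which excludes 0. That argues against RNA integrity as the whole cause, as far as these 3 measures capture it. The value lies under the bound written for that test, so a part from RNA integrity cannot be told apart. A biological difference between cirrhosis and steatosis stays open and was not tested.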

How the results depend on the processing

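The fits with stretches, with the GAPDH probe difference and without hepatitis samples 11 and 12 were chosen after seeing the data, and the cause of a change was not tested unless said otherwise. Signal over background limits what can be seen in dim genes. Of the 13648 tested genes, 1063 had a mean above the brightest nonspecific control (7.16 on the log2 scale), and all 13648 lay above the median of the control means (1.88). Over all alternatives, 201 counts stayed within 1.5 times and 48 counts or correlations did not. Of the values of named genes, 3309 kept direction and side of the threshold, 288 lost the call, 63 gained it and 68 changed sign, and of those of lists 1860 kept both, 231 lost the call and 11 changed sign. Camera with an estimated correlation called 0 lists in each comparison. With the steatosis samples split 3 and 3, the correlation of fold changes was 0.24, where fewer samples stand behind each value.

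In hepatitis against steatosis, array weights gave 4 genes (AXIN1, NCAM2, SPIRE1 and ZNF844, singled out after their values were seen) and 14 lists, 10 of them higher, and leaving out the 8 arrays of high spread in relative log expression gave 12 lists, 10 of them higher, against 12 higher of 23. With array weights and without the 8 arrays, camera placed the B and plasma cell list lower than other genes, though its mean was 0.0257 and 0.0446. CRP, at -0.13, changed sign to 0.0296 with the median of a gene's probe sets, 0.52 with array weights, 0.0523 with the spread as a covariate, 0.68 without the 8 arrays, 0.0480 with the stretch as a block and 0.37 in the last stretch alone, without the first stretch or with cirrhosis from the second stretch only. CD163, at -0.12, was at 0.00379 with array weights, 0.0608 with the spread as a covariate, 0.24 without the 8 arrays and 0.0903 in the last stretch alone, without the first stretch or with cirrhosis from the second stretch only.

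In cirrhosis against steatosis, the number of genes was 1280 with array weights, 664 with the spread as a covariate, 586 without the 8 arrays, 98 with the GAPDH probe difference as a covariate, 38 with the stretch as a block, 55 in the last stretch alone, 1330 with cirrhosis from the second stretch only, and 75.5 as the median of 20 draws of 13 cirrhosis samples. These draws ran from 17 to 465 genes, some above the 257 of all samples. The count thus depended on which cirrhosis arrays were drawn and not only on their number. CRP was at -0.30 with the block and -0.41 in the last stretch alone, PLIN2 at 0.0806 with cirrhosis from the second stretch only, and CD163 at 0.0724 with the GAPDH covariate.

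In cirrhosis against hepatitis, the number of genes was 1618 with array weights, 956 with the spread as a covariate, 695 without the 8 arrays, 190 with a fold change of at least 1.5, 21.5 as the median of the draws, 3 with the stretch as a block, 61 in the last stretch alone, 52 in the first stretch alone, 1416 with cirrhosis from the second stretch only and 584 without hepatitis samples 11 and 12. The draws ran from 0 to 282 genes. The share of higher genes was 271 of 695 without the 8 arrays and 774 of 1618 with array weights, against 245 of 323. The lists called numbered 5 with the block, 6 in the last stretch alone, 19 with cirrhosis from the second stretch only and 5 with the GAPDH covariate. COL1A1 was at -0.21 with the median of its probe sets, -0.10 with the most variable probe set, -0.13 without the 8 arrays and -0.0954 without the first stretch. CRP was at -0.15 with array weights, -0.37 without the 8 arrays and -0.0515 without the first stretch. With the block, the bile acid list was at 0.0669, ALB at 0.10, CYP7A1 at 0.34, CRP at -0.35, COL1A1 at -0.0415, SPP1 at -0.35, CXCL8 at -0.61 and CD163 at 6.07e-04. In the last stretch alone, ALB was at 0.11, CYP7A1 at 0.22, CRP at -0.79, COL1A1 at -0.26, SPP1 at -0.49 and CXCL8 at -0.66. With the GAPDH covariate, the respiratory chain list was at 0.0855, ALB at 0.0428, CXCL8 at -0.0279 and CD163 at 0.12. Without hepatitis samples 11 and 12, CD163 was at 0.0944 here and PLIN2 at -0.0612 in hepatitis against steatosis.

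In the first stretch alone, the lists of drug metabolism, alcohol metabolism, bile acids, fatty acid oxidation, macrophages, sinusoidal endothelium and the respiratory chain were at 0.31, 0.37, 0.28, 0.40, 0.56, 0.0921 and 0.44. There ALB was at 0.0463, CYP2E1 at 0.24, CYP7A1 at 1.09, CXCL8 at -0.31, CD163 at 0.92, PLIN1 at 0.75, BBOX1 at 0.64, AKR1D1 at 0.32, CLEC1B at 0.0130, ADH4 at 0.22, PDK4 at 0.70 and AMACR at 0.27.

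The genes differing among the 3 groups numbered 2810 with array weights, 1585 with the spread as a covariate, 1368 without the 8 arrays, 61 with the stretch as a block, 103 in the last stretch alone, 1849 with cirrhosis from the second stretch only and 438 with the GAPDH covariate.

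Replicate numbers in the titles were not shown to pair samples: of 25 pairs of equal number, 9 had deviations that correlated over 0.1, with a median of 0.0152 and a range of -0.39 to 0.62. With the replicate number as a block, 0, 249 and 406 genes and 12, 20 and 19 lists (5, 9 and 7 of them higher) passed for hepatitis against steatosis, cirrhosis against steatosis and cirrhosis against hepatitis, and PLIN2 was at -0.38 in the first and 0.25 in the last of these. Leaving out each steatosis or hepatitis sample in turn gave 0 to 1, 63 to 283 and 205 to 463 genes and 17 to 24, 19 to 20 and 9 to 17 lists in the same order. Over these, CRP ran from -0.49 to 0.13 and CD163 from -0.24 to 0.00629 in hepatitis against steatosis, where PLIN2 ran from -0.0396 to 0.24. CRP ran from -0.0946 to 0.52 in cirrhosis against steatosis, and CXCL8 from -0.0126 to 0.45 in cirrhosis against hepatitis.

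Another normalization moved the share of higher genes. Quantile normalization again gave 122 higher of 194 in cirrhosis against steatosis and 324 of 482 in cirrhosis against hepatitis, and centring gave 114 of 237 and 171 of 287.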

Other observations

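The division of the arrays into stretches and the correlations without noisy arrays were chosen after the data were seen. Among the 67 cirrhosis samples, the bile duct and ductular list score went with the matrix and neutrophil chemokine scores. The correlation with the extracellular matrix score was r = 0.79 (Spearman's rho = 0.81), and that with the neutrophil chemokine score, which includes CXCL8, was r = 0.82 (rho = 0.80). Within the second stretch (31 samples) these were 0.75 and 0.80, and within the last (32 samples) 0.80 and 0.72, while the first holds 4 cirrhosis samples, too few for a value. Without the 2 samples farthest from the median ductular score they were 0.81 and 0.77. Of 6 relations computed, each had an adjusted permutation p at or below 0.0041. The permutations ran over all 67 samples and ignored the stretch, so a difference between stretches in both scores can lower these p-values. The r values had p = 1e-05, the smallest that 100000 resamples can give, for the drug metabolism, matrix and chemokine scores, and all 6 rho values did.

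A hypothesis written before its test was that ductular signal is higher where hepatocyte signal is lower. The ductular and drug metabolism scores of the 67 cirrhosis samples correlated with r = -0.55 (rho = -0.74, permutation p = 1e-05 and adjusted p = 2e-05 for r), and with r = -0.50 without the 2 samples farthest from the median ductular score. The permutations ignored the stretch, and these scores differed between the second and last stretches in opposite directions, so part of this r can come from the stretch. Within the last stretch r was -0.76 and within the second -0.21, which missed the bound of -0.3 written for both, but the second value rests on its noisiest arrays: without those above the noise limit of 0.820 it was -0.62 (n = 27), and that of the last stretch -0.78 (n = 31). Array quality is unlikely to be the whole cause, since r was -0.70 with the noise, GAPDH and ACTB measures taken out. With hepatocyte plasma proteins, transcription factors and bile acid genes r was -0.35, -0.35 and -0.48 over all samples, and within the second stretch 0.02, -0.10 and -0.10 with all arrays and -0.43, -0.68 and -0.65 without the noisy ones.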
